A study of Mus musculus with 12 samples.

How the data were processed

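Accessibility was measured by ATAC-seq in bone marrow-derived macrophages of C57Bl/6 background from wild-type (WT), Ifnar-/- and Irf1-/- mice. Per the labels' protocols, bone marrow came from age- and sex-matched mice, was cultured in L929-conditioned medium, was replated on day 4 and was stimulated with LPS on day 7 for 0, 1, 2 or 4 h. Nuclei were treated with the Tn5 transposase of an Illumina kit. Each of the 3 genotypes was measured once at each of the 4 times, which gives 12 libraries. The labels carry no replicate numbers and do not say whether the libraries of a genotype came from separate animals or cultures.

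The deposited table holds integer counts of reads in 89993 regions for the 12 libraries, with 1 common set of regions. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2, and Picard, MACS2 2.1.0 and deepTools were used. The tool that made the counts, the way peaks were merged and the filter on duplicates are not given in the sources used here. Regions were 200 to 4761 bp wide, with a median of 406 bp. The starts in the table count from 0 and were raised by 1 for the printed coordinates. All 12 count columns were used. The counts held at most 1.65 reads per base in the 4 mitochondrial regions and 1.00 elsewhere, so the number of positions per region may limit the mitochondrial counts. 46 regions lie on unplaced or mitochondrial sequence and were kept.

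The depth per library, the sum of its counts, ran from 3124361 (WT 0 h) to 5071538 (WT 4 h), a ratio of 1.62. The median region had 17 counts in WT 0 h and 30 in WT 4 h. At these depths a single region of median count is measured with wide counting error, and small changes in weak regions pass unseen. In simulated data with the real means and depths, the test of Irf1-/- against WT over all times recovered 52.2% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, with 4 false calls. The test of the late change recovered 11.9%, 26.9% and 72.7%, with 2 false calls. Changes were put only into regions above a minimum mean count. The simulated counts otherwise followed the additive model, with a spread that depended on abundance alone. Recovery in the real data may therefore be lower and false calls more frequent.

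Regions were linked to the nearest protein-coding gene of a table of 21900 genes on the same genome build, using the distance to the whole span of the gene, up to 100 kb. The plan had been to use the distance to the gene start, but the table gives no strand, so starts could not be told from ends. 84605 regions (94.0%) were linked, 61.1% overlapped a gene and 17.1% lay within 1 kb of a gene end. Motif tests and a correction for GC content need the genome sequence and were not run.

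Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Regions with at least 10 counts in at least 3 libraries were tested, 85534 in all. Library sizes were scaled by TMM, with factors from 0.983 to 1.02. CPM values, counts scaled to library size, use these sizes, and log2 differences use a prior count of 2. Tests were edgeR's robust quasi-likelihood F tests with Benjamini-Hochberg adjustment over all tested regions, and calls have an adjusted p under 0.05 without a fold limit. An additive model of genotype and time (6 residual and 67.4 prior degrees of freedom) gave the changes at 1, 2 and 4 h and the 3 genotype differences over all times. A second model of time, genotype and their interaction with a late phase (2 and 4 h against 0 and 1 h; 4 residual and 117 prior degrees of freedom) gave the late differences. Calls of a difference over all times do not say at which time it arose. The regions WT opened were chosen on 1 library per time and compared without a test, with exact Clopper-Pearson intervals of the conditional binomial for the counting error of each ratio. Intervals of shares of regions are exact binomial ones that treat regions as independent.

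The models, the tests, the gene lists and the rule for naming regions were set before the data were examined. Per comparison the text draws on the 10 regions with the smallest p in each direction that changed by at least 2-fold, in the same direction in every matched pair, with 1 region per gene. It also draws on up to 4 regions per gene list and on all regions linked to Irf1, Ifnar1 and Ifnar2. For single libraries the rule was the 10 largest ratios each way with at least 50 counts in the higher library.

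There were 17 lists, written from general knowledge of the genes. They hold antiviral interferon-stimulated genes (43 of 45 matched), GBP, IRG and other gamma-interferon-associated genes (33 of 36), antigen presentation (30), NF-kB-associated inflammatory genes (57), immediate early genes (39), macrophage identity (35), LXR, PPARG and sterol genes (30), glycolysis and hypoxia (28), TLR, interferon and JAK-STAT signalling (38) and housekeeping (30). The other 7 hold markers of neutrophils (19), B cells (14), T and NK cells (19), fibroblasts and stroma (17), dendritic cells (13), erythroid cells and megakaryocytes (14) and mast cells and basophils (10). Lists were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists within each of 9 comparisons, and again with an estimated correlation. Each list's median was also placed among those of 10000 random lists of regions matched on mean count.

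Alternatives were DESeq2 1.42.0, scaling by total counts or relative log expression, an abundance-trended offset, no filter, a model without the time term, fits to only the compared libraries, hours as a linear term, the 4 h library alone as late, other limits for the regions WT opened, closer links to genes, and leaving out each library in turn. A count without windows dense in calls was added after the data had been seen. Shared WT libraries were examined by simulating all 12 libraries, WT included, with both knockouts set against the same simulated WT (20 simulations for the correlation, 5 for the overlap). For all times the simulated genotypes were equal. For the late change they kept their differences over all times but had no late difference. Each knockout was also given its own pair of WT libraries. For the overlap all knockout libraries were kept. For the correlations each knockout was also limited to the times of its WT pair. Each comparison was repeated on all other splits of its libraries into groups of the same size. The scripts were tested on simulated data.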

Results

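Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse bone marrow-derived macrophages grown in L929-conditioned medium. The cells came from wild-type mice (WT), mice lacking the type I interferon receptor (Ifnar-/-) and mice lacking the transcription factor IRF1 (Irf1-/-). They were left unstimulated or were stimulated with 100 ng/mL of lipopolysaccharide (LPS), the ligand of the receptor TLR4, for 1, 2 or 4 h. Each of the 3 genotypes was sampled once at each of the 4 times, which made 12 libraries. The total counts in regions were 3124361, 4690223, 4146049 and 5071538 in WT at 0, 1, 2 and 4 h. They were 3728116, 4308210, 3785312 and 3994255 in Ifnar-/- and 3996557, 4436401, 4421844 and 4710543 in Irf1-/-. Of 89993 regions, 85534 were tested, with a median count of 25 per library.

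The p-values rest on 1 library per genotype and time, without replicate cultures. Times served as blocks for the genotypes and genotypes as blocks for the times, and departures from the additive model supplied the error. That error does not measure the spread between animals or cultures of a genotype. A genotype difference can therefore not be told apart from a difference between the animals or cultures used. LPS separated the libraries along the first principal component, which held 45.2% of the variance. The second held 11.5%. Libraries of the same time correlated across regions at 0.922 to 0.956, and unstimulated with stimulated libraries at 0.814 to 0.863. Accessibility is given in CPM (counts scaled to library size) as mean ± SD, and differences as log2 ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test. Regions carry the name of the nearest protein-coding gene, which does not show that they act on it. Coordinates are on mm10.

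The loci of the deleted genes were examined first. The region at the Irf1 gene (chr11:53769635-53770725) held 46.9, 51.4, 69.0 and 60.5 CPM in WT at 0, 1, 2 and 4 h and 44.8, 55.5, 68.2 and 62.9 CPM in Irf1-/-, a difference of 0.03 ± 0.06 (adjusted p = 0.957). A smaller region inside Irf1 (chr11:53775805-53776109) was higher in all 4 Irf1-/- libraries, at 6.51, 5.05, 8.10 and 7.74 CPM against 2.55, 3.05, 4.19 and 4.10 CPM in WT (0.95 ± 0.22, adjusted p = 0.00355). A region 18.4 kb from Irf1 (chr11:53796776-53797241) opened to 13.1 CPM in WT at 1 h and to 6.42 CPM in Irf1-/-, and over all times was lower in Irf1-/- (-0.75 ± 0.16, adjusted p = 0.000992). In all, 3 of 14 tested regions linked to Irf1 differed between Irf1-/- and WT.

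At Ifnar1, an intragenic region (chr16:91493467-91493935) held 9.30, 9.37, 8.05 and 7.31 CPM in Ifnar-/- at 0, 1, 2 and 4 h. The same region held 0.319, 0.653, 0.493 and 0.780 CPM in WT and 0.751, 1.38, 0.463 and 0.627 CPM in Irf1-/-. The difference between Ifnar-/- and WT was 3.77 ± 0.32 (adjusted p = 1.57e-14). Another region, 8.82 kb from Ifnar1 (chr16:91475724-91476213), held 18.8 ± 3.29 CPM in Ifnar-/- against 5.41 ± 1.13 CPM in WT (n = 4 each; 1.81 ± 0.16, adjusted p = 1.36e-14). A region 20.7 kb away was lower in Ifnar-/- (-1.10 ± 0.23, adjusted p = 0.00269). The main region in the gene (chr16:91484830-91485773) differed by 0.07 ± 0.06 (adjusted p = 0.847). Of the regions tested, 3 of 12 linked to Ifnar1 and 0 of 6 linked to Ifnar2 differed between Ifnar-/- and WT, and 0 of 12 linked to Ifnar1 differed between Irf1-/- and WT. The deleted exons are not given in the sources used here, so accessibility at these loci does not by itself check the genotype labels.

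The first comparison asked which regions LPS opened or closed, with the 3 genotypes as blocks. After 1 h the region at Tnf, which encodes a proinflammatory cytokine (chr17:35199786-35202449), rose from 64.1 ± 3.36 to 212 ± 5.1 CPM (n = 3 genotypes; 1.73 ± 0.05, adjusted p = 4.32e-34). A region in Nfkb1, which encodes an NF-kB subunit (chr3:135640081-135640677), rose from 1.05 ± 0.474 to 30.6 ± 1.29 CPM (4.89 ± 0.23, adjusted p = 5.54e-29). A region in Nod2, a sensor of bacterial cell wall fragments (chr8:88649950-88650678), rose by 3.28 ± 0.16. Regions at Peli1, a ubiquitin ligase (2.81 ± 0.12), Ccrl2, an atypical chemokine receptor (1.90 ± 0.09), and Il12b, which encodes a subunit of interleukin-12 (1.79 ± 0.09), rose too, as did those at Mtmr7 (3.12), Alpk2 (2.70), Hivep3 (2.61) and Phldb1 (1.86). Closing was smaller in size. A region 13.9 kb from Hint1 (chr11:54884426-54885369) fell from 45.2 ± 0.868 to 16.3 ± 0.721 CPM (-1.47 ± 0.11, adjusted p = 1.48e-19), and regions at Lrp5, a coreceptor of Wnt signalling (-1.93 ± 0.16), Eloc (-1.46), St6gal1 (-1.28), Pik3c3 (-1.49), Tbc1d1 (-1.15), Ppp1r13b (-1.33), Trmt1 (-1.67), Osgin1 (-1.46) and 3110082I17Rik (-1.07) fell.

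At 2 h a region at the chemokine gene Ccl5 (chr11:83530313-83530823) had risen from 1.24 ± 0.594 to 34.9 ± 3.49 CPM (n = 3; 4.83 ± 0.22, adjusted p = 7.52e-30). Regions at Eml2 (4.50 ± 0.21), Nod2 (3.49), Mtmr7 (3.0), Peli1 (2.82), Hivep3 (2.79) and Cdc37 (2.58) were also open. Regions at Hs3st1 (-1.88), Pex5 (-1.36), 2900026A02Rik (-2.31) and Cnrip1 (-1.92) had closed. At 4 h the region at Ccl5 stood at 31.8 ± 5.64 CPM (4.68 ± 0.22, adjusted p = 3.81e-28). A region 89.2 kb from Ptgs2, the gene of an inducible prostaglandin synthase (chr1:150197482-150198268), had risen from 2.07 ± 0.996 to 33.0 ± 0.241 CPM (3.95 ± 0.19). A region in Acod1, the gene of the enzyme that makes itaconate (chr14:103046740-103047386), had risen from 3.94 ± 1.67 to 38.6 ± 5.75 CPM (3.23 ± 0.16). Rnf145 (2.66), Foxn3 (3.49) and Gm28710 (4.93) were further genes with opened regions. Among closed ones, the region in Tbc1d1 (chr5:64336762-64337546) fell from 40.6 ± 1.57 to 10.5 ± 0.839 CPM (-1.94 ± 0.12, adjusted p = 5.37e-23), and that in Vsir, an immune checkpoint gene, from 19.1 ± 0.667 to 3.65 ± 1.42 CPM (-2.42 ± 0.20). Hs3st2 (-1.80) and Itgb5 (-1.18) were also among genes with closed regions.

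By gene group, of 513 tested regions of NF-kB-associated inflammatory genes, 310 rose and 14 fell at 1 h (324 and 16 adjusted over the list alone), with a median of 0.71. The list stood above other regions by camera (adjusted p = 6.21e-32 with the preset correlation and adjusted p = 0.0179 with an estimated correlation). At 2 h 303 rose and 14 fell (322 and 20 over the list alone; adjusted p = 0.0264 with an estimated correlation), and at 4 h 263 rose and 27 fell (275 and 34; adjusted p = 0.0407 with an estimated correlation). Of 163 regions of antiviral interferon-stimulated genes, 48 rose and 3 fell at 1 h (50 and 4 adjusted over the list alone), among them regions at Usp18, a deconjugase of ISG15 (3.09), Parp14 (1.60) and the RNA sensor Ifih1 (0.97). At 2 h 99 rose and 0 fell (103 and 1), and at 4 h 92 rose and 1 fell (94 and 1), with Usp18 at 3.56 ± 0.24 and Oasl1 at 2.59. Camera gave this list adjusted p = 8.31e-05, 3.52e-20 and 1.61e-14 at 1, 2 and 4 h with the preset correlation, and adjusted p = 0.398, 0.166 and 0.186 with an estimated correlation.

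Of 146 regions of guanylate-binding protein (GBP), immunity-related GTPase (IRG) and other gamma-interferon-associated genes, 56, 79 and 76 rose at 1, 2 and 4 h and 6, 3 and 3 fell (58, 83 and 80 risen over the list alone). Examples were Gbp5 (1.51 at 1 h), Il15 (3.53 at 1 h) and Gbp6 (2.56 at 4 h). The list was called at each time with the preset correlation (adjusted p = 1.7e-06, 3.53e-16 and 2.44e-13) and not with an estimated correlation (adjusted p = 0.188, 0.0843 and 0.162). Antigen presentation genes had 32 of 116 regions risen and 9 fallen at 1 h (adjusted p = 0.14), and 47 risen and 7 fallen at 2 h (adjusted p = 0.0023, and adjusted p = 0.166 with an estimated correlation). At 4 h 35 rose and 8 fell (adjusted p = 0.113), with H2-T24 at 3.07 and Cd40 at 1.5. Immediate early genes had 117 of 381 regions risen and 40 fallen at 1 h (adjusted p = 0.00673, and adjusted p = 0.188 with an estimated correlation), with Klf6 at 2.76 and Atf3 at 1.2. They had 97 risen and 47 fallen at 2 h (adjusted p = 0.121) and 75 and 62 at 4 h (adjusted p = 0.842). Regions of TLR, interferon and JAK-STAT signalling genes rose in 100 of 320 cases and fell in 34 at 2 h (adjusted p = 0.0244, and adjusted p = 0.0843 with an estimated correlation), but the list was not called at 1 h (86 and 38, adjusted p = 0.14) or 4 h (84 and 39, adjusted p = 0.115). Examples of this list were Socs3 (2.88 at 4 h), Irak3 (4.24 at 4 h) and Tirap (2.91 at 1 h).

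Macrophage identity genes had 83 of 395 regions risen and 64 fallen at 1 h (adjusted p = 0.664). LXR, PPARG and sterol genes had 41 of 205 risen and 43 fallen (adjusted p = 0.328), with Mylip at -1.60. Glycolysis and hypoxia genes had 29 of 217 risen and 35 fallen (adjusted p = 0.2), with Pfkfb3 at 2.00 and Hk2 at 1.73. Housekeeping genes had 7 of 103 risen and 14 fallen (adjusted p = 0.14). Among markers of other cell types, the neutrophil list was called at 2 h, when 15 of 55 regions had risen and 5 had fallen (adjusted p = 0.0394, and adjusted p = 0.166 with an estimated correlation). At 1 h the regions risen and fallen were 11 and 2 of 48 for B cells (adjusted p = 0.346), 10 and 3 of 53 for T and NK cells (adjusted p = 0.911), 13 and 4 of 54 for fibroblasts and stroma (adjusted p = 0.346) and 20 and 10 of 104 for dendritic cells (adjusted p = 0.398). They were 2 and 2 of 18 for erythroid cells and megakaryocytes (adjusted p = 0.398) and 8 and 0 of 30 for mast cells and basophils (adjusted p = 0.2).

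In total, 15655 regions rose and 10177 fell at 1 h, 15486 and 9837 at 2 h, and 15169 and 10629 at 4 h. Changes of at least 2-fold were made by 9675 of the regions that rose and 2236 of those that fell at 1 h. Of the regions higher at 1 h, 12571 (80.3%) were also higher at 2 h and 10620 (67.8%) at 4 h. Of those lower at 1 h, 6663 (65.5%) and 5743 (56.4%) were lower at 2 and 4 h. The 3 comparisons share the 0 h libraries, which adds to these overlaps. Independent lists of these sizes would share 2834 higher regions between 1 and 2 h. With DESeq2's Wald test the totals were 12778, 13067 and 12104 instead of 25832, 25323 and 25798.

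**Figure D1:**
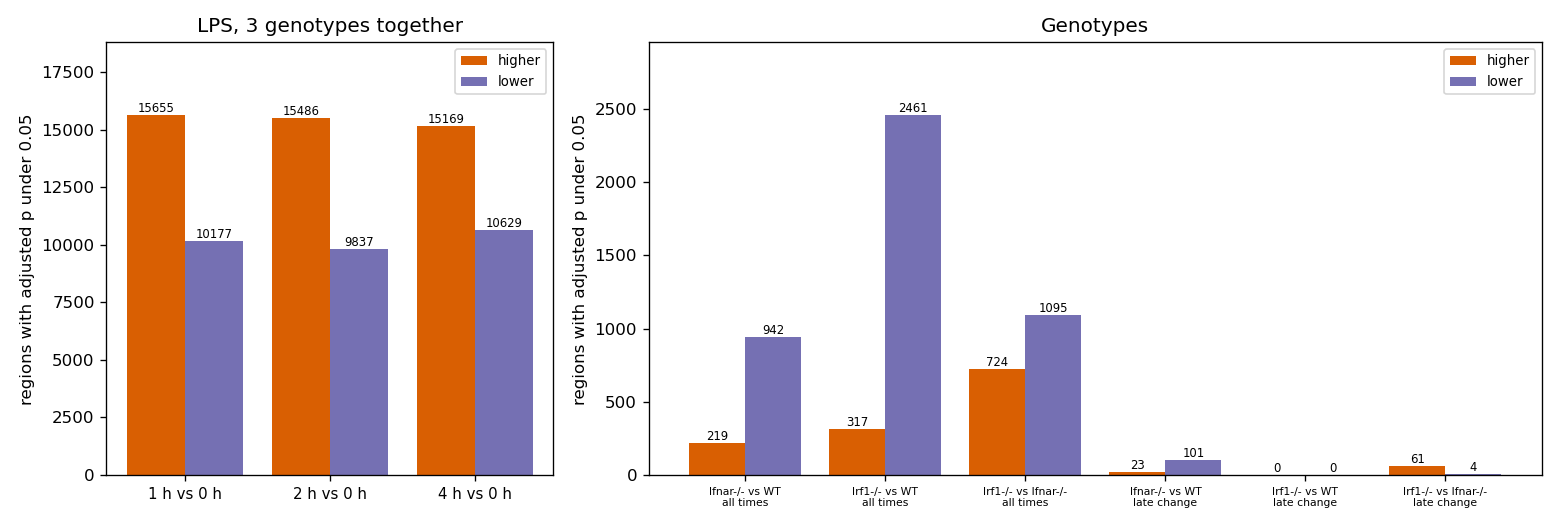
Number of regions higher and lower in each comparison at an adjusted p under 0.05 (edgeR's quasi-likelihood test). The left panel gives the LPS comparisons over 3 genotypes and the right panel the genotype comparisons, with 942 regions lower in Ifnar-/- and 2461 lower in Irf1-/- than in WT over all times and 0 called for the late change of Irf1-/- against WT.

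Over all 4 times, Ifnar-/- macrophages had lower accessibility than WT at single regions of antiviral and GTPase genes. A region in Oas1a, the gene of a synthetase that senses double-stranded RNA (chr5:120906777-120907764), held 2.80 ± 0.835 CPM in Ifnar-/- and 16.1 ± 5.92 CPM in WT (n = 4 each; -2.49 ± 0.19, adjusted p = 1.11e-16). Regions in the antiviral genes Trim30a (-2.41 ± 0.24, adjusted p = 4.13e-12), Herc6 (-1.45 ± 0.15, adjusted p = 7.94e-12) and Oas2 (-1.43 ± 0.15, adjusted p = 8.01e-11) were lower as well. The Oas1a and Oas2 regions lie in a window dense in calls (chr5, 120 to 125 Mb), where DNA of another strain is not excluded as a source. The region in Herc6 was not placed against such windows here, so the same source is not excluded for it. A region in Casp4, the sensor of intracellular LPS (chr9:5311506-5312056), held 6.64 ± 2.90 CPM against 16.5 ± 6.14 CPM (-1.28 ± 0.16, adjusted p = 1.38e-08), and regions at Tgtp1 (-1.84) and Gbp2 (-1.83) were lower.

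The strongest single differences included regions at genes of other kinds. A region 35.0 kb from Adcyap1r1 (chr6:55536439-55537191) held on average 1.51 CPM in Ifnar-/- and 17.6 ± 1.02 CPM in WT (-3.57 ± 0.23, adjusted p = 4.28e-19). A region 75.1 kb from Vgll3 (chr16:65739570-65740079) had 0 counts in the 4 Ifnar-/- libraries, 165 in the WT and 166 in the Irf1-/- libraries. With a floor of 3 counts over the group, 0.191 CPM, it was at least 51.1-fold lower than in WT. Regions at 1810024B03Rik (-2.19), C77080 (-2.45), Mindy4 (-1.94), Slc9c1 (-2.61), Tgm3 (-1.95) and BC016579 (-3.23) were lower. A region near Gm52481 on chrY was lower too (-1.69), but it lies next to sequence shared with chrX, so its counts are uncertain. Higher in Ifnar-/- were a region in Avl9 (chr6:56757870-56758532; 14.8 ± 2.27 against 2.06 ± 0.392 CPM; 2.80 ± 0.21, adjusted p = 1.33e-17) and regions at Rngtt (1.62), Caln1 (2.77), Ttc3 (2.71), Vinac1 (3.07), Ndfip2 (2.74), Arhgap31 (3.05), Ccdc62 (3.26) and Vps26c (1.80). Of the 1161 called regions, 229 (19.7%) lay in 9 windows of 5 Mb that hold 2.87% of the tested regions, among them the window of Ifnar1 (33 of 350 regions called) and that of the Oas genes on chr5 (35 of 392). The regions at Adcyap1r1, Avl9 and Mindy4 lie in another (chr6, 55 to 60 Mb, 27 of 129), and that at 1810024B03Rik in one on chr2 (125 to 130 Mb, 21 of 363). That in Cd86, named below, lies in a further one (chr16, 35 to 40 Mb, 20 of 210).

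Of 163 regions of antiviral interferon-stimulated genes, 0 were higher and 51 lower in Ifnar-/- (90 lower adjusted over the list alone), with a median of -0.47. Camera gave adjusted p = 3.14e-59 with the preset correlation and adjusted p = 0.122 with an estimated correlation. Of 146 GBP, IRG and gamma-interferon-associated regions, 22 were lower (48 over the list alone; median -0.26; adjusted p = 1.66e-18, and adjusted p = 0.122 with an estimated correlation). Antigen presentation genes had 9 of 116 regions lower (16 over the list alone; adjusted p = 3.02e-05, and adjusted p = 0.122 with an estimated correlation). They included the costimulatory gene Cd86 (-0.88), Nlrc5, a transactivator of MHC class I genes (-1.16), and the immunoproteasome subunit Psmb10 (-0.42). NF-kB-associated genes had 7 of 513 regions higher and 2 lower (adjusted p = 0.206), with Nfkbiz at 2.02 and Il1b at 0.75. TLR, interferon and JAK-STAT signalling genes had 2 higher and 9 lower (adjusted p = 0.396), with Stat3 at -1.59 and Irf2 at -0.76. In the macrophage identity list 1 region was higher and 6 were lower (adjusted p = 0.959), including the sialic acid receptor gene Siglec1 (-2.20). Immediate early genes had 4 lower (adjusted p = 0.883), with Hes1 at -2.32, and glycolysis and hypoxia genes 4 lower (adjusted p = 0.644), with Hif1a at -0.98. LXR, PPARG and sterol genes had 1 lower (Ch25h, -0.73; adjusted p = 0.644), housekeeping genes 3 lower (adjusted p = 0.257), and marker lists of 7 other cell types between 0 and 2 lower, the smallest adjusted p being 0.0508 for dendritic cells.

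Altogether, 219 regions were higher and 942 lower in Ifnar-/- than in WT, 91 and 423 of them by at least 2-fold. DESeq2's Wald test called 208, and a model without the time term called 100. Without 1 library the count was 562 (WT 2 h), 467 (WT 4 h), 620 (Ifnar-/- 2 h) and 481 (Ifnar-/- 4 h), against 1705 without Ifnar-/- 1 h.

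In Irf1-/- macrophages most differences from WT were losses of accessibility. A region in Cd86, which encodes a costimulatory ligand (chr16:36598135-36598858), held 3.20 ± 1.74 CPM in Irf1-/- and 21.6 ± 9.16 CPM in WT (n = 4 each; -2.77 ± 0.18, adjusted p = 2.38e-17). A region 14.0 kb from Plg, the plasminogen gene (chr17:12363699-12364586), held 7.93 ± 3.23 against 31.7 ± 12.8 CPM (-2.00 ± 0.11, adjusted p = 5.6e-24). A region 12.1 kb from Ddit4l (chr3:137610635-137611615) held 1.91 ± 0.453 against 15.4 ± 1.55 CPM (-3.01 ± 0.20, adjusted p = 1.19e-19), and one 20.6 kb from Bloc1s4 (chr5:36726333-36726770) held 1.60 ± 0.883 against 15.1 ± 7.62 CPM (-3.23 ± 0.22, adjusted p = 1.28e-18). A region in Pcgf5, a Polycomb group gene (-1.94 ± 0.14), and one near the complement gene C6 (-2.10 ± 0.15) were lower as well.

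The lowest adjusted p belonged to a region 3.01 kb from Mid1 (chrX:169993809-169994897), with 2.62 ± 0.506 CPM in Irf1-/- and 36.7 ± 7.56 CPM in WT (-3.80 ± 0.14, adjusted p = 5.32e-35). Mid1 spans the boundary of the pseudoautosomal region, where chrX and chrY share sequence, and how shared reads were counted is not given in the sources used here, so this value is uncertain, as are those of a lower (-1.60) and a higher (2.30) region near Gm52481 on chrY. Regions at Btnl10 (-1.31) and Trim17 (-2.74) lay in the single 5 Mb window dense in calls (chr11, 55 to 60 Mb, 43 of 240 regions called), next to the 5 Mb window that holds Irf1 (9 of 317). Regions higher in Irf1-/- were fewer. They included one in Robo2 (3.98 ± 1.76 in WT, 12.9 ± 8.33 CPM in Irf1-/-; 1.68 ± 0.19, adjusted p = 3.82e-10), one near Me2, the gene of a mitochondrial malic enzyme (5.59 ± 2.05 in WT, 15.1 ± 2.19 CPM in Irf1-/-; 1.46 ± 0.17), and regions at Malrd1 (1.19), 1700009N14Rik (1.81), Gnas (1.62), Hand1 (1.56), 2210407C18Rik (1.90), Khdrbs1 (1.48) and Sel1l3 (1.11).

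**Figure D2:**
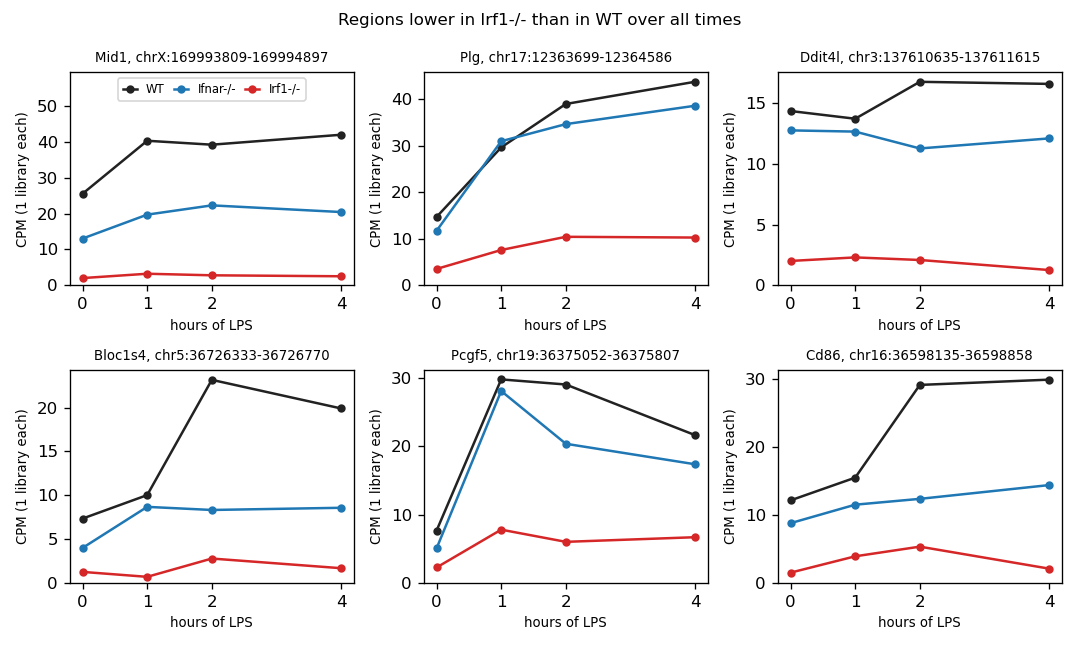
Accessibility in CPM at 0, 1, 2 and 4 h of LPS for 6 regions that were lower in Irf1-/- than in WT over all times, with 1 library per point and 1 line per genotype. The region in Cd86 averaged 21.6 CPM in WT, 11.7 CPM in Ifnar-/- and 3.20 CPM in Irf1-/-.

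Of 146 GBP, IRG and gamma-interferon-associated regions, 0 were higher and 30 lower in Irf1-/- (40 lower adjusted over the list alone), with a median of -0.19. Camera gave adjusted p = 7.73e-16 with the preset correlation and adjusted p = 0.162 with an estimated correlation. Examples were the transcription factor gene Batf2 (-1.18 ± 0.12, adjusted p = 1.91e-11), Gbp4 (-2.27 ± 0.26, adjusted p = 4.73e-10), Gbp6 (-2.08) and Gbp10 (-2.38). Of 163 antiviral interferon-stimulated regions, 11 were lower (16 over the list alone; median -0.08; adjusted p = 8.39e-06, and adjusted p = 0.569 with an estimated correlation), such as Phf11d (-0.89), Ifi47 (-1.42), Cmpk2 (-1.11) and Ifih1 (-1.08). Antigen presentation genes had 8 of 116 regions lower (12 over the list alone; adjusted p = 8.39e-06, and adjusted p = 0.162 with an estimated correlation), among them Nlrc5 (-2.22), Psmb10 (-0.68) and Tapbpl (-0.53).

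The other lists were not called in Irf1-/- (smallest adjusted p = 0.214). NF-kB-associated genes had 13 of 513 regions higher and 17 lower (adjusted p = 0.511), with the scavenger receptor gene Marco at 0.57, Il12a at -1.37, Il12b at -0.77 and Tnfaip3, a brake on NF-kB, at -1.19. TLR, interferon and JAK-STAT signalling genes had 4 higher and 15 lower (adjusted p = 0.696), with Stat3 at -2.38, Stat4 at -1.75, Jak1 at -1.2 and Tbk1 at -1.95. The macrophage identity list had 13 of 395 lower (adjusted p = 0.692), including Irf8, which encodes a myeloid transcription factor (-2.05 ± 0.34, adjusted p = 7.43e-06), Zeb2 (-1.81) and the efferocytosis receptor gene Mertk (-2.98). Immediate early genes had 10 lower (adjusted p = 0.994), among them Dusp16 (-2.44) and Egr2 (-2.55), and glycolysis and hypoxia genes 8 lower (adjusted p = 0.214), among them Pfkfb3 (-3.82 ± 0.54, adjusted p = 2.28e-07) and Hk1 (-0.71). LXR, PPARG and sterol genes had 1 higher (Insig2, 0.38) and 1 lower (Ch25h, -0.55; adjusted p = 0.371), and housekeeping genes 2 lower (Ywhaz, -1.47, and Srsf5, -0.45; adjusted p = 0.371). Among markers of other cell types, 4 of 54 fibroblast and stromal regions were lower (adjusted p = 0.696), including Prrx1 (-2.01) and Cxcl12 (-2.19), and the neutrophil marker Ltf was lower (-2.60) while Mmp8 was higher (0.78; list adjusted p = 0.371). The dendritic cell list had 1 lower (Zbtb46, -1.52; adjusted p = 0.511), and the B cell list 1 higher (Bank1, 1.81; adjusted p = 0.692). T and NK cell markers had 1 higher (Bcl11b, 1.21) and 1 lower (Ncr1, -0.78; adjusted p = 0.494). Erythroid and mast cell lists had 0 called in edgeR's test (list adjusted p = 0.517 and 0.214).

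Altogether, 317 regions were higher and 2461 lower in Irf1-/- than in WT, 80 and 1506 of them by at least 2-fold. DESeq2's Wald test called 971, and a model without the time term 175. Without 1 library the count was 1751 (WT 2 h), 1394 (WT 4 h) and 1636 (Irf1-/- 4 h) in place of 2778.

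**Figure D3:**
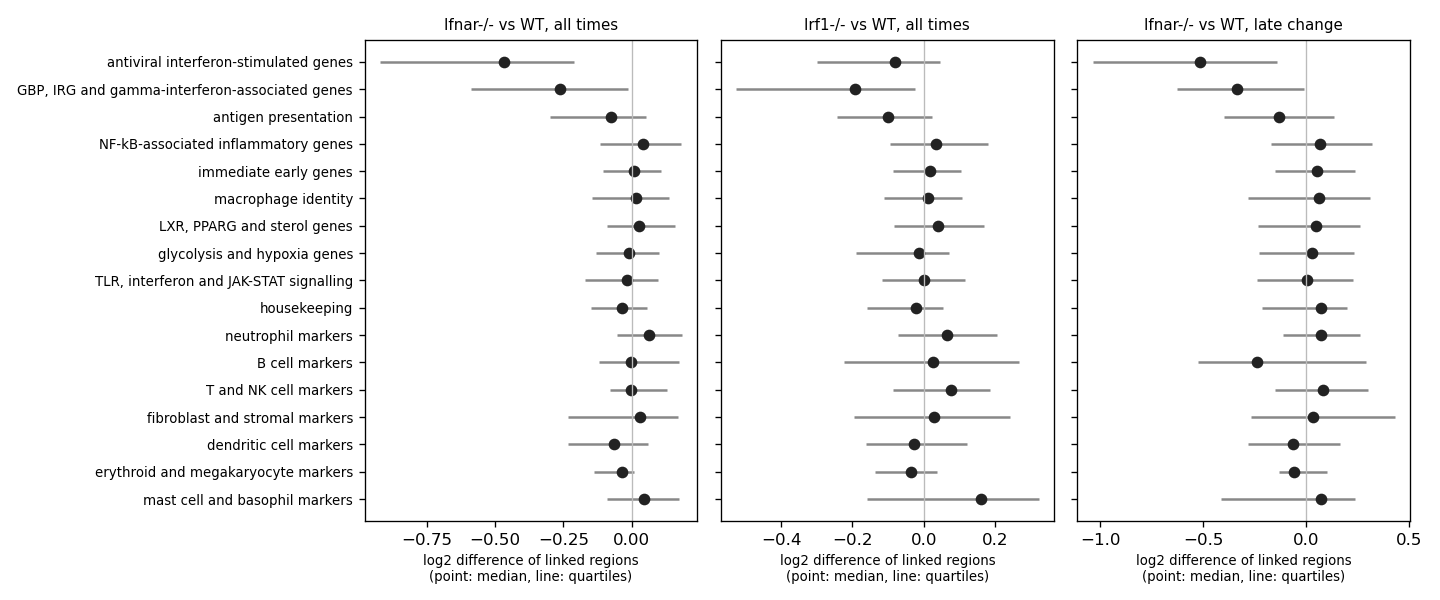
Median (points) and quartiles (lines) of the log2 difference of the tested regions of each of 17 gene lists, for Ifnar-/- against WT over all times, Irf1-/- against WT over all times, and the late change of Ifnar-/- against WT. Antiviral genes have medians of -0.47, -0.08 and -0.51 in the 3 panels.

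Regions lower in both knockouts numbered 352, of 942 lower in Ifnar-/- and 2461 lower in Irf1-/-. Independent lists of these sizes would share 27.1. Simulated libraries of equal genotypes, with a simulated WT shared by both knockouts, had 0 calls in each of 5 simulations. Those simulations therefore give no chance value for the overlap. When each knockout was set against its own pair of WT libraries, 35 were shared between lists of 255 and 1696, against 5.06 for independent lists. Regions higher in both numbered 17, against 0.812 for independent lists. Across the 85534 regions the knockouts' differences from WT correlated at Pearson's r = 0.481 and Spearman's rho = 0.494. Unchanged groups with shared WT libraries gave r = 0.504. The covariance was 0.0391 against a simulated 0.0227, a difference of 0.0163. The simulations left out the extra spread that the quasi-likelihood test fits to each region. The difference therefore does not by itself show an effect shared by the knockouts. With the libraries split by time, r was 0.148. There Ifnar-/- and WT were compared at 0 and 2 h only, and Irf1-/- and WT at 1 and 4 h only. The fall in r can therefore not be credited to the shared WT libraries alone. Regions are not independent replicates, and part of the overlap may stem from the shared WT libraries.

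Set directly against each other, the knockouts differed at single antiviral genes. The region in Oas1a, for example, held 17 ± 4.91 CPM in Irf1-/- and 2.80 ± 0.835 CPM in Ifnar-/- (n = 4 each; 2.59 ± 0.19, adjusted p = 2.88e-18). Regions at Trim30a (2.35 ± 0.24), Herc6 (1.47 ± 0.14), Oas2 (1.40 ± 0.15), Casp4 (1.23 ± 0.16) and Siglec1 (2.39 ± 0.34) were also higher in Irf1-/-. Those in Oas1a and Oas2 lie in the window dense in calls on chr5, so DNA of another strain is not excluded as a source of their differences. The regions at Herc6 and Siglec1 were not placed against the dense windows here, so the same source is not excluded for them. Cd86 went the other way, with 3.20 ± 1.74 CPM in Irf1-/- and 11.7 ± 2.32 CPM in Ifnar-/- (-1.89 ± 0.22, adjusted p = 4.89e-09). A region in Slamf8 (12.7 ± 6.02 against 31.5 ± 15.0 CPM; -1.31 ± 0.11) and one 33.3 kb from Nos2, the inducible nitric oxide synthase gene (-0.91 ± 0.12, adjusted p = 3.17e-07), were lower in Irf1-/-.

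Further regions higher in Irf1-/- lay at C77080 (30.0 ± 4.61 against 3.08 ± 0.685 CPM; 3.28 ± 0.16, adjusted p = 3e-27), Azin2 (2.14), 1810024B03Rik (2.48), Phc2 (2.82), Fam167b (2.53), Adcyap1r1 (3.43) and Slc9c1 (2.76). The region near Vgll3 was at least 49.8-fold lower in Ifnar-/-, and a region in Aunip (chr4:134512821-134513221) had 1 count in the Ifnar-/- libraries together and 42 to 49 counts in each Irf1-/- library. Lower in Irf1-/- were regions at Plg (-1.87), Rngtt (-1.97), Avl9 (-2.57), Btnl10 (-1.16), Ddit4l (-2.67), Trim17 (-2.37), Tent5b (-2.42) and Ifnar1 (-2.12), and the uncertain region near Mid1 (-2.83). Of these calls, 307 of 1819 (16.9%) lay in 9 windows of 5 Mb dense in calls. Many of the regions named here lie in such windows. Those at C77080, Azin2 and Fam167b share a window (chr4, 125 to 130 Mb, 35 of 268 regions called), and that in Aunip lies in the next (61 of 412). Those at 1810024B03Rik (chr2), Adcyap1r1 and Avl9 (chr6), Btnl10 and Trim17 (chr11) and Ifnar1 (chr16) lie in others. DNA of another strain is therefore not excluded as a source of their differences.

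Of 163 antiviral interferon-stimulated regions, 31 were higher in Irf1-/- than in Ifnar-/- and 0 lower (60 higher adjusted over the list alone; median 0.29; adjusted p = 3.32e-30, and adjusted p = 0.633 with an estimated correlation). GBP, IRG and gamma-interferon-associated genes had 9 of 146 regions higher and 10 lower (adjusted p = 0.944), with Batf2 at -0.83 and Socs1, a feedback inhibitor of cytokine signalling, at 0.33. Antigen presentation genes had 1 higher (Tap1, 0.45) and 3 lower (adjusted p = 0.805), including Nlrc5 (-1.44) and Cd80 (-0.84). NF-kB-associated genes had 13 higher and 12 lower (adjusted p = 0.805), with Marco at 1.12, Nfkbiz at -1.65 and Il1b at -1.42. Macrophage identity genes had 5 higher and 7 lower (adjusted p = 0.922), with Mpeg1 at 0.68 and Csf1r, the receptor of macrophage colony-stimulating factor, at -0.63. The other 12 lists were not called either (smallest adjusted p = 0.745).

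In this comparison 724 regions were higher and 1095 lower in Irf1-/- than in Ifnar-/-, 321 and 700 of them by at least 2-fold. DESeq2's Wald test called 547 and a model without the time term 195. Without Irf1-/- 2 h the count was 1051 and without Irf1-/- 4 h it was 922, in place of 1819.

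The series title names ISGF3, the complex formed downstream of the interferon receptor, so the late change, from 0 and 1 h to 2 and 4 h of LPS, was compared between genotypes as an interaction. In Ifnar-/- several regions that opened late in WT stayed near their starting level. At Ifit2, an interferon-induced antiviral gene (chr19:34577013-34578401), WT held 2.87, 5.01, 47.8 and 61.1 CPM at 0, 1, 2 and 4 h. Ifnar-/- held 2.66, 6.09, 2.95 and 4.03 CPM and Irf1-/- 3.50, 5.28, 31.0 and 45.8 CPM. The late change differed between Ifnar-/- and WT by -4.11 ± 0.41 (adjusted p = 1.03e-12). At Rsad2, which encodes the antiviral protein viperin (chr12:26441596-26442799), the difference was -2.77 ± 0.27 (adjusted p = 2.31e-12). WT reached 57.4 and 64.0 CPM at 2 and 4 h, and Ifnar-/- 11.3 and 6.30 CPM. At Cxcl10, an interferon-inducible chemokine gene (chr5:92346892-92349191), WT held 14.3, 105, 174 and 109 CPM and Ifnar-/- 15.7, 96.3, 69.2 and 44.6 CPM, so that the genotypes parted only after 1 h (-1.21 ± 0.11, adjusted p = 2.39e-13).

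A region 1.60 kb from Tmprss2 (chr16:97561502-97563082) reached 66.0 CPM in WT and 71.0 CPM in Irf1-/- at 2 h but 1.34 CPM in Ifnar-/- (-5.03 ± 0.56, adjusted p = 4.89e-11). The region near Irgm1, the gene of an immunity-related GTPase (chr11:48862940-48864607), reached 45.3 CPM in WT, 31.9 CPM in Irf1-/- and 5.37 CPM in Ifnar-/- at 2 h (-2.75 ± 0.39, adjusted p = 2.97e-06). Bace2 (-4.04 ± 0.56), Cmpk2 (-4.22 ± 0.77), Art3 (-2.09 ± 0.22), Gbp5 (-1.68 ± 0.28), Dtx3l (-1.49), Trim56 (-1.36), Iigp1 (-1.45) and Oas3 (-1.14) were further genes with a smaller late change in Ifnar-/-.

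The opposite was measured at other genes, among them Cxcl2 and Cxcl1, which encode neutrophil-attracting chemokines. The region in Cxcl2 (chr5:90904624-90905116) held 2.87, 25.7, 8.62 and 3.12 CPM in WT at 0, 1, 2 and 4 h and 2.39, 19.7, 18.0 and 20.7 CPM in Ifnar-/- (2.15 ± 0.31, adjusted p = 1.99e-05). At Cxcl2 the late change of Irf1-/- also lay above that of WT, without being called, so the direction was not particular to Ifnar-/-. At Cxcl1 (chr5:90890824-90891686), WT held 4.15, 25.7, 13.6 and 10.5 CPM and Ifnar-/- 4.25, 19.9, 20.7 and 23.7 CPM (1.2 ± 0.26, adjusted p = 0.0163). The region in Mrnip, a DNA repair gene, fell to 8.39 CPM at 4 h in WT and stood at 30.0 CPM in Ifnar-/- (1.49 ± 0.24, adjusted p = 0.000182). Lrrc74a (1.04), Mctp1 (1.67), Hmgxb3 (1.65), Mmd (1.25), Vrk3 (1.85) and Chchd10 (1.08) were other genes with a higher late change, as was a region near Gm52481 on chrY (1.14) whose counts are uncertain.

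**Figure D4:**
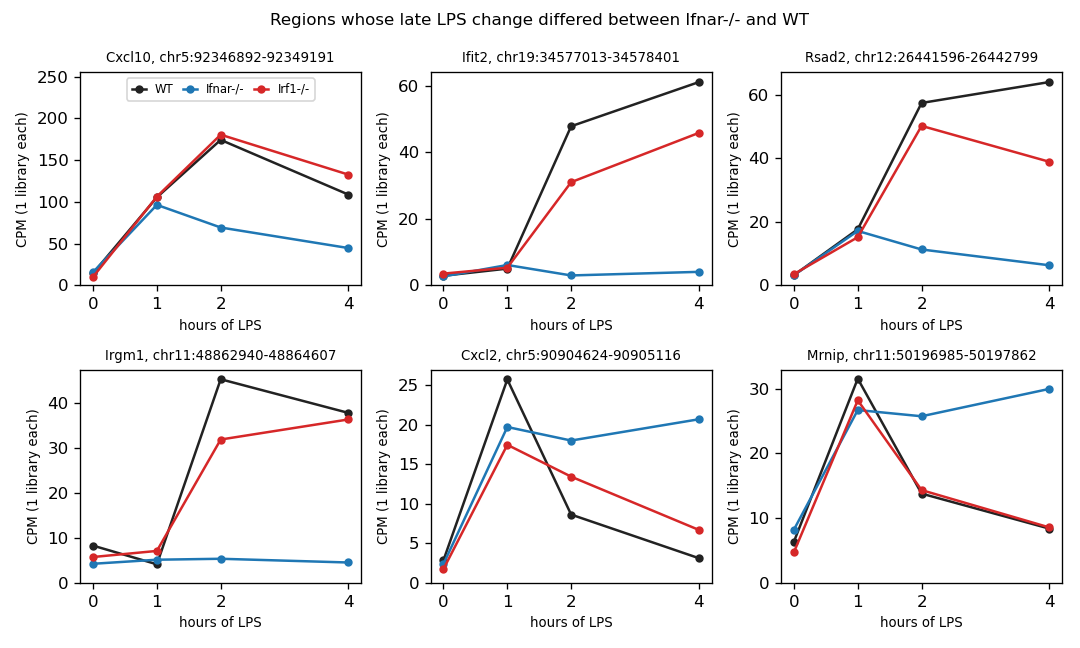
Accessibility in CPM at 0, 1, 2 and 4 h of LPS for 6 regions whose late change differed between Ifnar-/- and WT, with 1 library per point and 1 line per genotype. At Ifit2 the WT and Irf1-/- lines reach 61.1 and 45.8 CPM at 4 h and the Ifnar-/- line 4.03 CPM, while at Cxcl2 the Ifnar-/- line stands at 20.7 CPM and the WT line at 3.12 CPM.

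Of 163 antiviral interferon-stimulated regions, 11 had a lower and 0 a higher late change in Ifnar-/- (42 lower adjusted over the list alone), with a median of -0.51. Camera called this list with the preset correlation (adjusted p = 1.02e-29) and with an estimated correlation (adjusted p = 0.00688). GBP, IRG and gamma-interferon-associated genes had 4 of 146 regions lower (9 over the list alone; median -0.33; adjusted p = 2.69e-09, and adjusted p = 0.0885 with an estimated correlation). Antigen presentation genes had 1 of 116 lower (H2-T24, -0.89; 4 over the list alone; adjusted p = 0.00449, and adjusted p = 0.305 with an estimated correlation). NF-kB-associated genes had 3 of 513 higher (adjusted p = 0.143), and signalling genes 3 of 320 lower (Tlr3, -1.14, Irf2, -0.90, and Tlr7, -0.92; adjusted p = 0.692). The macrophage gene Fcgr1 (-1.31; list adjusted p = 0.652) and the dendritic cell marker Tcf4 (-1.55; list adjusted p = 0.417) were lower. The other 10 lists had 0 regions called in edgeR's test, the smallest list adjusted p being 0.417.

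In Irf1-/-, no region was called for a late change other than that of WT. edgeR's quasi-likelihood test gave 0 regions, with 3853 (4.50%) at an unadjusted p under 0.05, and DESeq2 gave 0. In simulated data the same test recovered 26.9% of 2-fold and 72.7% of 4-fold late changes. A difference from WT that was already present at 1 h counts in the baseline of this test. Antiviral genes had a median of 0.03 (adjusted p = 0.913) and GBP, IRG and gamma-interferon-associated genes one of -0.08 (adjusted p = 0.71). Single values stood at -0.47 ± 0.18 for Usp18 (adjusted p = 1), -2.14 ± 0.71 for a region near Gbp4 (adjusted p = 0.936), -2.31 ± 0.80 for a second region in Cd86 (chr16:36602622-36602988; adjusted p = 0.985) and 1.38 ± 0.34 for Cxcl2 (adjusted p = 0.578). Without Ifnar-/- 4 h the count was 2. The late changes of both knockouts against WT correlated at r = 0.516 (rho = 0.483). Simulated libraries with a shared WT, genotype differences over all times and no late difference gave 0.501. Their covariance exceeded the simulated one by 0.00987, in simulations with the same limit on spread as above. With Ifnar-/- and WT limited to 0 and 2 h and Irf1-/- and WT to 1 and 4 h, r was 0.00994. That value compares different times, so it does not show how much the shared WT libraries add.

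Between the knockouts, the late change was larger in Irf1-/- at Cxcl10 (1.40 ± 0.11, adjusted p = 7.06e-17), Rsad2 (2.47 ± 0.28), Ifit2 (3.46 ± 0.41), Gbp5 (2.45 ± 0.29), Irgm1 (2.34 ± 0.39), Ifit1bl1 (3.07 ± 0.50), Oas3 (1.17 ± 0.19), Tmprss2 (4.59 ± 0.54), Bace2 (4.12 ± 0.57) and Art3 (2.07 ± 0.21). It was smaller at Mrnip (-1.23 ± 0.25, adjusted p = 0.00758) and at Ifitm10 (-1.54 ± 0.33, adjusted p = 0.0167). Antiviral genes had 14 of 163 regions higher (44 adjusted over the list alone; median 0.55; adjusted p = 7.16e-36, and adjusted p = 0.00225 with an estimated correlation). GBP, IRG and gamma-interferon-associated genes had 4 higher (10 over the list alone; median 0.20; adjusted p = 3.49e-05, and adjusted p = 0.221 with an estimated correlation). Signalling genes had 1 higher (Tlr3, 1.01; adjusted p = 0.778). The remaining 14 lists had 0 regions called, the smallest list adjusted p being 0.338.

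In all, 23 regions had a higher and 101 a lower late change in Ifnar-/- than in WT, and 61 a higher and 4 a lower one in Irf1-/- than in Ifnar-/-. DESeq2's Wald test called 6 and 7. With only the 4 h library as late, 173 regions were called for Ifnar-/- against WT, 142 higher and 31 lower, and 19 of them were shared with the 124. With hours as a linear term 209 were called, 125 higher and 84 lower. Between the knockouts, the 4 h library alone as late gave 6 higher and 34 lower regions, so the main direction turned there too. The count of 124 became 41 without WT 0 h, 24 without WT 1 h, 42 without WT 4 h, 66 without Ifnar-/- 0 h, 5 without Ifnar-/- 1 h, 278 without Ifnar-/- 2 h and 37 without Ifnar-/- 4 h. The count of 65 became 37, 11 and 125 without Ifnar-/- 0, 1 and 2 h and 21 and 31 without Irf1-/- 1 and 4 h.

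A last comparison took regions opened by LPS in WT and measured them in the knockouts. The 1612 regions that opened at least 4-fold from 0 to 4 h in WT, with the lower bound of the interval above 2-fold, had a median log2 change of 2.56 in WT, 1.91 in Ifnar-/- and 1.90 in Irf1-/- at 4 h. At 1 h the medians were 2.06, 1.64 and 1.55, and at 2 h 2.52, 1.85 and 1.95. In Ifnar-/- 339 of the regions (21.0%, 95% exact Clopper-Pearson interval 19.1 to 23.1%) opened by less than 2-fold at 4 h, and in Irf1-/- 356 (22.1%, 20.1 to 24.2%). The change was lower in Ifnar-/- than in Irf1-/- by at least 2-fold in 206 regions (12.8%) and higher in 251 (15.6%), a balance that turned for regions opened by at least 2-fold (932 and 889) and for those chosen on 2 h against 1 h (43.3% and 18.3%). Choosing regions on the WT libraries favours WT in this comparison, and no test was made. The intervals of these shares treat regions as independent draws and leave out the counting error of each region's change. For 60 regions chosen on 2 h against 1 h in WT, the share under 2-fold from 0 to 4 h was 13.3% in WT, 61.7% in Ifnar-/- and 36.7% in Irf1-/-. For regions opened by at least 2-fold it was 43.2% in Ifnar-/- and 40.6% in Irf1-/-.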

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

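The tests at Cxcl1 and Cxcl2 for DNA of another strain, and for Irf1-/- those of an effect before LPS and of low depth in WT 0 h, were chosen after the results had been seen. The other tests in this part were chosen before. The results listed first were singled out because a test found the late LPS change, at 2 and 4 h against 0 and 1 h, to differ between genotypes.

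The late change differed between Ifnar-/- and WT in 124 regions and between Irf1-/- and Ifnar-/- in 65. Against WT it was lower in Ifnar-/- at Cxcl10 (-1.21), Ifit2 (-4.11), Rsad2 (-2.77), Art3 (-2.09), Tmprss2 (-5.03), Bace2 (-4.04), Irgm1 (-2.75), Trim56 (-1.36), Dtx3l (-1.49) and Gbp5 (-1.68). It was higher at Cxcl2 (2.15), Mrnip (1.49), Cxcl1 (1.2), Lrrc74a (1.04), Mctp1 (1.67), Hmgxb3 (1.65), Mmd (1.25), Gm52481 (1.14), Vrk3 (1.85) and Chchd10 (1.08). Between the knockouts it was higher in Irf1-/- at Cxcl10 (1.40), Art3 (2.07), Tmprss2 (4.59), Rsad2 (2.47), Ifit2 (3.46), Gbp5 (2.45), Bace2 (4.12), Ifit1bl1 (3.07), Irgm1 (2.34) and Oas3 (1.17), and lower at Mrnip (-1.23) and Ifitm10 (-1.54). Of the gene lists, antiviral genes (median -0.51), GBP, IRG and gamma-interferon-associated genes (-0.33) and antigen presentation genes (-0.13) had a lower late change in Ifnar-/- than in WT, but with an estimated correlation only the antiviral list was called (adjusted p = 0.00688, 0.0885 and 0.305). Antiviral (0.55) and GBP, IRG and gamma-interferon-associated genes (0.20) had a higher one in Irf1-/- than in Ifnar-/-, the second not with an estimated correlation (adjusted p = 0.221).

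A first pattern is that differences between Ifnar-/- and WT over all times lie partly in blocks of the genome. In 9 windows of 5 Mb lay 19.7% of the calls, just under the share set beforehand, which leaves DNA of another strain carried along with the deleted gene undecided. Of these windows, 4 lie on chr16, where Ifnar1 lies, and 5 on other chromosomes, and the one with most calls (35) holds the Oas genes. An abundance-trended offset removed 0.873% of those calls, under the share set beforehand, so a depth bias that follows abundance did not make them. The offset leaves the depth and counting error of each library as they were, so other effects of depth were not tested. Outside the windows, antiviral and GBP list regions were over-represented among lower calls, with an odds ratio of 30.9 (22.6 to 41.7; 60 of 284 list regions), which is consistent with absent interferon signalling. That interval treats regions as independent, and with an estimated correlation neither list was called over all times (adjusted p = 0.122 each).

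A second pattern is that Irf1-/- had many regions lower over all times and no called late difference. Over 2433 regions chosen on 1, 2 and 4 h, the median log2 ratio of Irf1-/- to WT was -0.92, -1.19 and -1.28 at those times. At 0 h, which was not used to choose them, it was -0.43 (-0.45 to -0.39, regions taken as independent). Of the regions 77.3% lay below 0, and the median over all regions was 0.00528. A smaller difference was thus measured before LPS, in 1 library per genotype. It was 37.3% of that after LPS, so whether an effect before LPS accounts for the pattern is undecided. With Ifnar-/- 0 h in place of WT 0 h the median was -0.29 (-0.33 to -0.26), which the limits set leave undecided. The 2433 regions were chosen without any 0 h library, which argues against low depth of WT 0 h as the source of their difference after LPS. Without WT 0 h the late test of Irf1-/- against WT also called 0 regions. That count cannot decide why late calls were missing, since leaving out a library lowers the power of a test that already had 0 calls. Whether low depth of WT 0 h adds to the difference at 0 h stays undecided. Of the lower calls, 1.42% lay in a dense window, under the share set beforehand against DNA of another strain as the main source. A window counted as dense only above 31 calls, against 16 for Ifnar-/-, so sparser blocks would be missed. This cause is therefore not excluded. The dense window (chr11, 55 to 60 Mb, 43 of 240 regions called) lies next to the one that holds Irf1. Too little power of the late test stays possible, with 26.9% of simulated 2-fold late changes recovered. The late test also takes 1 h together with 0 h, so a difference already present at 1 h (median -0.92) counts in its baseline. The absence of late calls therefore does not show that the LPS response was the same in Irf1-/- and WT.

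Another pattern is that sites at Cxcl1 and Cxcl2 stayed accessible at 2 and 4 h in Ifnar-/-. The late change of Irf1-/- at Cxcl2 also lay above that of WT but was not called. At these 3 sites the median log2 ratio of Ifnar-/- to WT at 0 and 1 h was -0.0949 (-0.38 to 1.97), which leaves DNA of another strain at this locus undecided. Among 721 regions that rose at 1 h and fell by 4 h in the Irf1-/- libraries, the median late difference between Ifnar-/- and WT was 0.28 (0.24 to 0.32), against 0.0150 over all regions, with 0.0363 (-0.0027 to 0.0754) at 2 h and 0.45 at 4 h. A slower loss of early LPS sites in general is undecided: 3 of these regions were called higher and 0 lower.

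Each comparison was set against all other splits of its libraries. For LPS the splits were too few to exclude chance: in 1 of 10 splits, the real one, there were as many calls, with 25832, 25323 and 25798 calls at 1, 2 and 4 h and 0 in the highest other split. The genotype models match libraries by time, and only 8 of the 35 splits keep 1 library of each time in each group, too few to exclude chance. Over all 35 splits, as many calls as in the real split came in 1 for Irf1-/- against WT (2778 calls, highest other 1223, and 1146 among the matched ones). They came in 1 of 35 for Irf1-/- against Ifnar-/- (1819, highest other 306, and 303 among the matched ones) and in 2 of 35 for Ifnar-/- against WT (1161, highest other 1413, and 257 among the matched ones). For late changes they came in 4 of 34 splits for Ifnar-/- (124, highest other 1065) and in 3 of 34 between the knockouts (65, highest other 1874), so chance could not be excluded. The late change of Irf1-/- had 0 calls, so all 34 of 34 splits call as many and nothing is tested (highest other 2592). Splits that exchange the late libraries of both genotypes turn a genotype difference over all times into a late one.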

How the results depend on the processing

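No alternative here was chosen after its result had been seen, except the count without dense windows. Libraries were matched by time or genotype in the models, and no matching by replicate number could be made, since the labels carry none. Motif tests and the GC correction were not run. Where a value moved, the cause was not tested unless fewer libraries or another contrast explain it. No named result reversed its direction, but the balance of both late counts turned with the definition of late. In simulated data at the real depths, 86.6% of 2-fold changes were recovered over all times and 26.9% in the late test. These shares hold for regions above a minimum mean count that follow the additive model.

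With DESeq2's Wald test, 12778, 13067 and 12104 regions changed at 1, 2 and 4 h of LPS, in place of 25832, 25323 and 25798. It called 208 for Ifnar-/- against WT (1161 in edgeR's test), 971 for Irf1-/- against WT (2778) and 547 between the knockouts (1819). For late changes it called 6 for Ifnar-/- (124), 0 for Irf1-/- (0) and 7 between the knockouts (65). Without the time term, which leaves the LPS response in the error, these genotype counts were 100, 175 and 195. With scaling by total counts 14988 regions rose and 11756 fell at 1 h. No scaling moved the share of higher calls by over 10 points.

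Fitting only the compared libraries gave 81 late differences of Ifnar-/- against WT. Hours as a linear term gave 209 for Ifnar-/- (125 higher and 84 lower, against 23 and 101), of which 63 were shared with the 124, 1 for Irf1-/- and 40 between the knockouts. The 4 h library alone as late gave 173 for Ifnar-/- (142 higher and 31 lower) and 40 between the knockouts (6 higher and 34 lower, against 61 and 4).

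Without 1 library, the regions changed ranged from 19996 to 26461 at 1 h, 19374 to 25845 at 2 h and 19503 to 25718 at 4 h of LPS. The range was 467 (without WT 4 h) to 1705 (without Ifnar-/- 1 h) for Ifnar-/- against WT, 1394 (without WT 4 h) to 3007 (without Ifnar-/- 4 h) for Irf1-/- against WT and 922 (without Irf1-/- 4 h) to 1880 (without WT 4 h) between the knockouts. Late differences ranged from 5 (without Ifnar-/- 1 h) to 278 (without Ifnar-/- 2 h) for Ifnar-/-, 0 (without WT 0 h) to 2 (without Ifnar-/- 4 h) for Irf1-/- and 11 (without Ifnar-/- 1 h) to 125 (without Ifnar-/- 2 h) between the knockouts.

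Of the regions WT opened, the share under 2-fold in Ifnar-/- was 21.0%. It was 43.2% for regions opened by at least 2-fold, 61.7% for those chosen on 2 h against 1 h, 23.7% with a prior count of 5 and 23.8% with an abundance-trended offset. In Irf1-/- it was 22.1%, and 40.6%, 36.7% and 25% under the first 3 of these. Of 153 list tests, 25 were called with the preset correlation, 5 with an estimated correlation, 27 with genes within 10 kb and 40 with regions within 1 kb of a gene end. The late changes of both knockouts correlated at 0.516, and at 0.00994 with the WT and knockout libraries split by time, which compares different times. Without the windows dense in Ifnar-/- calls, Ifnar-/- against WT had 137 higher and 712 lower regions, Irf1-/- against WT 295 and 2397, and the knockouts 494 and 977.

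Of the named results, DESeq2 weakened 23 of 29 late ones of Ifnar-/- against WT, 28 of 56 of Ifnar-/- against WT, 15 of 64 of Irf1-/- against WT, 17 of 53 between the knockouts and 2 of 84 at 1 h of LPS. Leaving out Ifnar-/- 1 h weakened 25 of 29 late ones of Ifnar-/- against WT, and 4 h alone as late 22 of 29. Without the time term 33 of 56, 47 of 64 and 29 of 53 weakened. Over all 470, 2 did with an abundance-trended offset, 1 with total counts and 0 without the filter.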

Other observations

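No test in this part was chosen after its result had been seen, and the values of the first 2 paragraphs come from single libraries without a test, with exact intervals for counting error only. In WT from 0 to 4 h, a region 23.5 kb from Fpr2, the gene of a formyl peptide receptor, rose from 1 to 98 counts (log2 ratio 4.62, 3.39 to 11.22), and one near Heatr9 from 3 to 144 counts (4.31, 3.30 to 7.17). Regions near Ifitm10 (-2.65, -3.44 to -2.13) and in Vsir (-2.63) were lower at 4 h. At 4 h, Ifnar-/- exceeded WT in Lpp (2.74, 1.99 to 4.36), Cxcl2 (2.55, 1.94 to 3.60) and Gsta3 (1.97, 1.31 to 2.99). It was below WT near Tmprss2 (-4.69, -6.78 to -3.90), near Ppm1k, with 1 count against 60 (-4.06, -10.87 to -3.0), and near Adcyap1r1 (-3.62, -6.05 to -2.73).

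In Irf1-/- at 4 h, the region in Cd86 had 10 counts against 153 in WT (-3.56, -4.92 to -2.92) and one in Tbc1d9 had 9 against 132 (-3.47, -4.93 to -2.81). Higher than in WT were regions near Me2 (1.95, 1.32 to 2.96), in Abcb1a, a drug efflux pump gene (1.2, 0.53 to 2.08), and near Marco (1.16, 0.52 to 2.00). Before LPS, Irf1-/- was below WT in the nucleic acid sensor gene Zbp1 (-1.52, -2.41 to -0.84) and in the GTPase gene Iigp1 (-1.22, -1.97 to -0.60), and above it in Aff1 (1.47, 0.97 to 2.07). At 0 h, Ifnar-/- stood apart from WT at Avl9 (2.77, 1.90 to 4.38) and Adcyap1r1 (-3.57, -6.00 to -2.63), about as far as at 4 h.

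Gene list medians over all libraries were also placed among 10000 random lists matched on mean count, which treats regions as independent. The antiviral list stood at percentile 0 for Ifnar-/- against WT, 0 for Irf1-/- against WT and 78.0 for the late change of Irf1-/-. The GBP, IRG and gamma-interferon-associated list stood at percentiles 0, 0 and 0.36, though camera did not call its late change (adjusted p = 0.71). Low percentiles were not particular to these lists: the housekeeping list stood at 0.86 for Ifnar-/- and 0.81 for Irf1-/- against WT, and dendritic cell markers at 0.19 for Ifnar-/-. In the 4 mitochondrial regions the total per library varied 1.07-fold, while the total over all regions varied 1.62-fold.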
